A study of Mus musculus with 3 samples.

How the data were processed

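The deposited files hold raw UMI counts per gene and barcode for 3 mouse testis libraries, 1 per group, made with 10x Genomics 3' chemistry per the labels' protocols. The count matrices were written by Cell Ranger 5.0.1, per the file headers. The submitters' processing notes name Cell Ranger, Seurat and the build GRCm38, with no role for Seurat; whether any step after barcode calling touched the deposited counts is not given in the sources used here. Every deposited barcode had at least 500 UMIs. All 55450 genes had the same identifier and symbol in the GENCODE mouse annotation of GRCm38, from which coordinates were taken. The tissue is testis per the labels, while the wording of their extraction protocol speaks of aorta; the germ, Sertoli-like and Leydig-like cells in the files are those of testis. Replicate spread cannot be measured with 1 library per group, and the number of animals behind a library is not given in the sources used here.

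Cells with at least 500 UMIs, at least 300 genes and at most 20% mitochondrial UMIs were kept, which removed 243 PBS, 366 EXO and 641 dEXO barcodes. Doublets were called with Scrublet per library in scanpy 1.11.5 at its automatic threshold, and the calls were removed. It called 4 PBS, 2 EXO and 149 dEXO cells, where loading would give 4.22%, 7.89% and 7.30%. In PBS and EXO the caller therefore did not work, and doublets remained; clusters c15 and c20 mixed immune with Leydig markers and stayed unnamed. Removing the 222, 778 and 665 cells with the highest scores was run as an alternative. Counts were scaled to 10000 per cell and log-transformed; 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering (leidenalg 0.10.2, igraph 0.11.9) at resolution 1 gave 32 clusters over the 3 libraries together. No batch correction was made, since library and group are the same thing here. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0, and figures matplotlib 3.10.9.

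Clusters were named from markers of 18 classes. The markers were fixed before the data were examined, with round and elongating spermatids as separate classes. A name needed at least 3 raised markers, a marker of its own or of a related class among the 50 leading genes, no lead of another class among the top 10, and no second unrelated class; clusters with a median UMI count under 0.333 of the library's median in every library they came from needed an own marker among the top 10, a limit c11 lay above in EXO and dEXO. The naming rule, unlike the markers, was revised after clusters and shares had been seen, and 3 versions were run; the last is used, and the first 2 are among the alternatives. Round and elongating spermatids, apart in the first 2 versions, were joined as 1 class after the clusters had been seen, because they shared clusters. In the last version 7 clusters stayed unnamed, holding 18.8% of PBS, 14.7% of EXO and 12.8% of dEXO cells. One of them, c5, led by Cpz, Csrp2 and Tnnt2, also carried Leydig markers, and another, c28, combined protamine genes with Sertoli markers. Several clusters came mostly from 1 library, such as c9 from PBS and c2 from dEXO, so a cluster may be that library and not a cell type.

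Shares of cells carry exact Clopper-Pearson intervals. For gene levels, counts were summed per library and class and given as CPM, which scales each count to the total of its library and class, and each log2 ratio of CPM carries an exact conditional binomial interval of the 2 Poisson counts. A count of 0 was replaced by a floor of 3 counts in the ratio itself, and the bound was taken from its interval. Classes needed at least 100 cells in both libraries; Sertoli-like cells, macrophages, spermatogonia, spermatids and peritubular myoid cells, with fewer in PBS, were set against PBS from 50 cells on where the other library had them too, a choice made after seeing the data. Genes needed 50 UMIs over both libraries. Where scaling by the median gene moved values by over 0.1, values are given relative to the median gene. Gene lists, 25 in all, were fixed before the data were examined, and a list's median was placed among 10000 random lists of the same size matched on mean expression, which describes these libraries and is no test. The text gives a selection of the results of the 25 lists, and some lists outside the central 95% of random lists in a class are left out.

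The genes named were set by a rule fixed before the data were examined. Per pair of libraries, in up to 5 classes with most cells, the 3 highest and 3 lowest genes were taken by the interval bound nearest 0, leaving out mitochondrial, ribosomal protein and haemoglobin genes and predicted or clone-named ones. In the library where it was higher, a gene had to reach 0.25 of its level in the highest class with 100 cells or more, as a guard against free RNA. This guard could not see PBS macrophages and dendritic cells, which were under 100 cells. Up to 4 members of each list with the largest absolute ratio, and all steroidogenesis genes, could be named too. Early spermatocytes, Sertoli-like cells and macrophages are described by their lists alone. Values of steroidogenesis genes and of lists within single clusters were added after the values of the whole class had been seen, and Ldhc, a germ cell marker, is given as a measure of free germ cell RNA.

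The ratio, interval and list steps were tested on simulated counts for dEXO against PBS over 17588 genes. Of 17388 unchanged genes, 95.6% had intervals that held the true value and 4.42% had intervals that excluded 0. With 50 genes each, the median estimate was 0.59 for a 1.5-fold rise, -1.02 for a fall to 0.5, 1.03 for a 2-fold and 1.97 for a 4-fold rise. Among 100 unchanged lists 2 fell outside the central 95% of random lists, and among 100 lists raised 1.5-fold 100 did. The simulated counts were Poisson draws, the assumption on which the intervals rest, so this checks the calculation alone. It covers counting error and says nothing of the spread between cells or between animals.

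The alternatives were no cell filter, a stricter one (1000 UMIs, 500 genes, 10% mitochondrial UMIs), no doublets removed, the highest doublet scores removed, Leiden resolution 0.5 and 2, 4000 variable genes with 50 components, each library clustered alone, cells named one by one, and cells thinned to 1000 UMIs. Thinning left out 226 PBS, 888 EXO and 1119 dEXO cells. For gene levels they were scaling by the median gene, cells weighted equally, other UMI minimums (10 and 200) for the steroidogenesis list and, for single genes, subtraction of the estimated free RNA. That estimate was 1.82%, 1.54% and 2.91% of UMIs in Leydig-like cells and 1.45%, 2.59% and 4.38% in stromal-like cells, in the order PBS, EXO, dEXO. Markers of T or NK cells set it in EXO and dEXO, but those of dendritic or B cells in PBS, so the estimates are not strictly comparable.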

Results

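Single cells from mouse testis were profiled by droplet sequencing of the 3' ends of their transcripts, with a molecular tag (UMI) on each captured RNA molecule. All animals had been made azoospermic with busulfan, an alkylating drug that kills dividing germ cells. One group then received the saline vehicle (PBS), another received exosomes, small membrane vesicles, from the blood of wild-type mice (EXO), and the last received blood exosomes from mice with an imbalanced gut microbiota (dEXO). There was 1 library per group, so every difference below lies between 3 libraries and has no replicate check; no p-value was computed, and every interval is a 95% interval that covers counting error only. The PBS library held 5514 barcodes and 97253862 UMIs, the EXO library 10228 barcodes and 91787154 UMIs, and the dEXO library 9760 barcodes and 96655663 UMIs. The median cell was deeper in PBS (7708 UMIs) than in EXO (3144.5 UMIs) or dEXO (2852 UMIs). After filtering, 5267, 9860 and 8970 cells were used.

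The first comparison asked which cells each library held, and how many germ cells were found after the 3 injections. Germ cells were scarcest in the PBS library, where 214 of 5267 cells carried a germ cell profile. They made up 4.06% of PBS cells (3.55 to 4.63), 12.1% of EXO cells (11.5 to 12.8) and 23.1% of dEXO cells (22.3 to 24.0). Spermatogonia, the mitotic germ cells that include the stem cells, took 1.79% of PBS cells, 1.93% of EXO cells and 3.76% of dEXO cells. Meiotic and later stages differed more between the libraries. Early spermatocytes took 0.380%, 2.17% and 4.25% of the cells, late spermatocytes 0.702%, 3.70% and 7.21%, and spermatids, the haploid cells that become sperm, 1.20%, 4.30% and 7.90%, each in the order PBS, EXO, dEXO. Part of this lay in clusters with few UMIs. In the same order, c11 gave 28 of 63, 318 of 424 and 536 of 709 spermatids. Cluster c17, with a median of 12.1% mitochondrial UMIs, gave 3 of 20, 139 of 214 and 253 of 381 early spermatocytes.

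**Figure D1:**
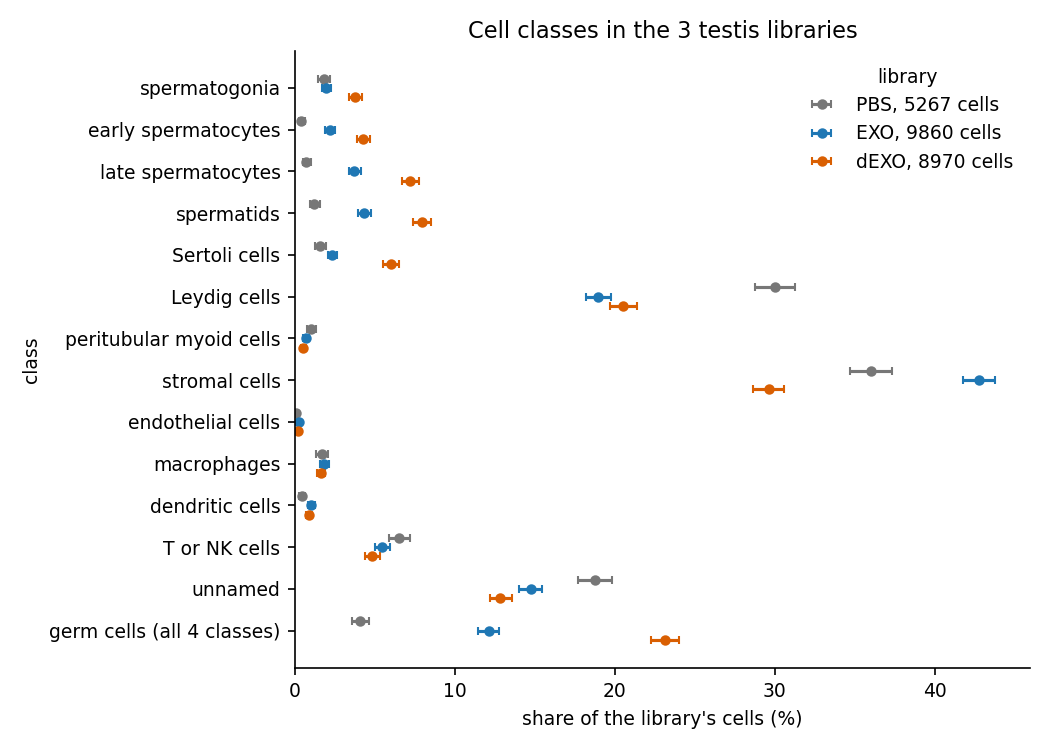
Share of each library's cells (x axis, percent) in each class (y axis); points are the shares of the 3 libraries and bars their exact 95% binomial intervals. Germ cells stand at 4.06% in PBS, 12.1% in EXO and 23.1% in dEXO, and Leydig-like cells at 30.02%, 19.0% and 20.5%.

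Among germ cells alone, the PBS library was made up mostly of spermatogonia and spermatids, while EXO and dEXO were closer to each other. Spermatogonia were 43.9% of the 214 PBS germ cells (37.2 to 50.9), against 15.9% of 1193 in EXO (13.9 to 18.1) and 16.2% of 2074 in dEXO (14.7 to 17.9). Late spermatocytes were 17.3% in PBS (12.5 to 23.035), 30.6% in EXO (27.99 to 33.3) and 31.2% in dEXO (29.2 to 33.2). Early spermatocytes were 9.35%, 17.9% and 18.4%. Spermatids were 29.4% in PBS (23.4 to 36.0), 35.5% in EXO (32.8 to 38.3) and 34.2% in dEXO (32.1 to 36.3), with overlapping intervals. Cluster c28, led by the protamine genes Prm1 and Prm2 and left unnamed because it also carried Sertoli markers, held 52 PBS, 22 EXO and 57 dEXO cells. Counted as spermatids, it takes that stage to 43.2% in PBS (37.2 to 49.4), 36.7% in EXO (33.99 to 39.5) and 35.9% in dEXO (33.9 to 38.03), so the direction of the spermatid difference depends on this cluster; spermatogonia are then 35.3%, 15.6% and 15.8%. The likeness of EXO and dEXO depended on the processing: the odds ratio of spermatogonia to later germ cells, dEXO to EXO, was 1.02 (0.840 to 1.25), but 0.619 (0.506 to 0.758) with each library clustered alone, where EXO held 263 spermatogonia and 639 later germ cells, and 1.27 (1.01 to 1.60) with no doublet removed.

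**Figure D2:**
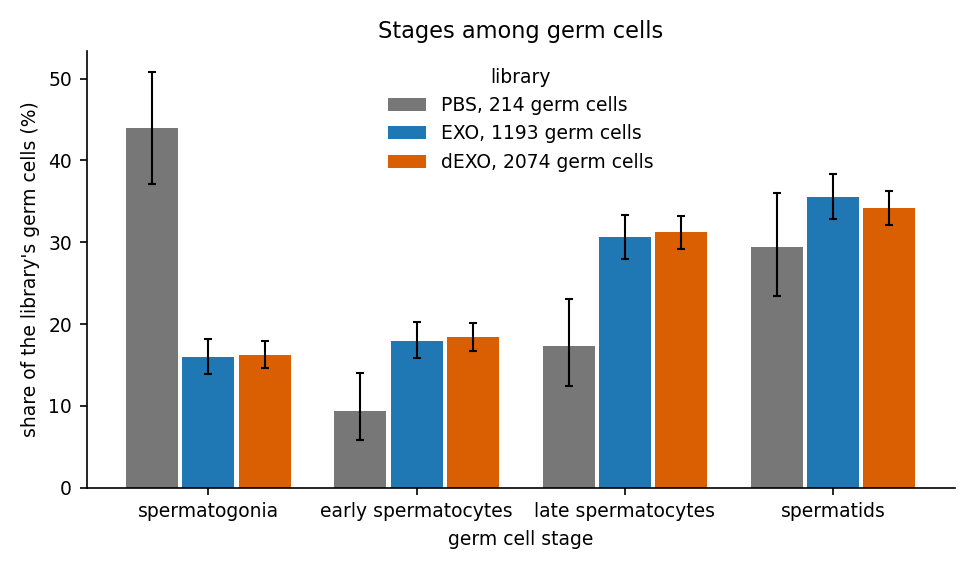
Share of each library's germ cells (y axis, percent) at each of 4 stages (x axis), with exact 95% binomial intervals as bars. The spermatogonia bar is 43.9% in PBS and 15.9% and 16.2% in EXO and dEXO.

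Sertoli-like cells, which nurse germ cells inside the tubule, were 1.54% of PBS cells (1.22 to 1.91), 2.31% of EXO cells (2.03 to 2.63) and 5.98% of dEXO cells (5.49 to 6.49). For each Sertoli-like cell there were 2.64 germ cells in PBS, 5.23 in EXO and 3.87 in dEXO. The odds ratio of germ to Sertoli-like cells was 1.98 for EXO against PBS (1.46 to 2.67), 1.46 for dEXO against PBS (1.1001 to 1.94) and 0.740 for dEXO against EXO (0.621 to 0.880). The ratios against PBS depended on the processing: over 13 other settings of naming, clustering, filtering, doublet removal and depth, the EXO to PBS ratio ran from 1.11 to 2.12 and the dEXO to PBS ratio from 0.693 to 1.58. Outside the tubule, testosterone-making Leydig-like cells were 30.02% of PBS cells (28.8 to 31.3), 19.0% of EXO cells (18.2 to 19.7) and 20.5% of dEXO cells (19.7 to 21.4). Unnamed c5, which also carried Leydig markers, held 572 PBS, 745 EXO and 282 dEXO cells. The order of EXO and dEXO in this share depends on whether c5 is counted. Stromal-like cells, the fibroblast-like cells of the interstitium, were 36.0% (34.7 to 37.3), 42.8% (41.8 to 43.8) and 29.6% (28.7 to 30.6). T or NK cells were between 4.82% in dEXO and 6.49% in PBS, and macrophages between 1.59% in dEXO and 1.82% in EXO. These macrophages are cluster c16 alone, led by Cd74 and H2-Eb1. Unnamed c15, which mixed macrophage genes such as Pf4 and C1qc with Leydig markers, held 138 PBS, 130 EXO and 150 dEXO cells. The macrophage shares therefore depend on whether c15 is counted. With every cell thinned to 1000 UMIs, the germ cell shares were 4.21%, 11.4% and 22.7%. Leaving out clusters c11 and c17, germ cells with few UMIs, moved the EXO share to 7.83% and the dEXO share to 15.7%, with PBS at 3.495%.

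The second comparison set the EXO library against the PBS library within cell classes. In Leydig-like cells the genes that make cholesterol, the raw material of testosterone, were lower in EXO without exception, while the testosterone pathway itself was nearly level as a group. All 19 cholesterol synthesis genes were lower, with a median log2 ratio of -0.45, below every one of 10000 random lists of like expression. Mvd (-1.04, -1.14 to -0.94), Sc5d (-0.76, -0.80 to -0.72), Lss (-0.69, -0.77 to -0.61) and Mvk (-0.61, -0.70 to -0.53), all enzymes of the pathway, were the farthest. Of 17 steroidogenesis genes, 8 were higher and 9 lower, with a median of -0.04 at percentile 38.4 of the random lists. Within c3, c9 and c21 the cholesterol list was at -0.30, -0.52 and -0.27.

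Single steroidogenic genes nonetheless differed between EXO and PBS Leydig-like cells. Nr4a1, a nuclear receptor induced within minutes by hormonal stimulation (chromosome 15, 101254269 to 101274795, GRCm38), was 9.95-fold higher in EXO (9.32 to 10.6), at 189.7 against 19.1 CPM (counts scaled to the total of the class). Hsd3b1, which oxidises pregnenolone, was higher at 0.73 (0.71 to 0.75), and Insl3, the Leydig cell hormone, at 0.50 (0.50 to 0.51). Srd5a1 (-0.87), the 5-alpha reductase, Por (-0.50), which feeds electrons to P450 enzymes, Cyp17a1 (-0.44), the 17-hydroxylase, and Scarb1 (-0.42), the receptor for high-density lipoprotein, were lower. Star, which carries cholesterol into mitochondria, stood at -0.15. Most PBS Leydig-like cells lay in cluster c9 (921 cells) and most EXO ones in c3 (1291 cells), but Nr4a1 was higher in EXO within each of the Leydig-like clusters that both libraries filled with 50 cells or more, at 3.84 in c3, 3.24 in c9 and 2.23 in c21. Insl3 was also higher, and Srd5a1, Por and Cyp17a1 lower, in each of these 3 clusters. Hsd3b1 was at 0.71 in c3 and 0.91 in c21 but at 0.064 (-0.030 to 0.16) in c9, Scarb1 at -0.45 in c3 but -0.15 (-0.37 to 0.064) in c9 and -0.015 (-0.30 to 0.28) in c21, and Star at -0.10 in c3, 0.011 in c9 and 0.21 in c21.

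Genes of cellular activation were lower in EXO than in PBS over the whole Leydig-like class, with smaller or opposite differences within its clusters. Of 19 immediate early genes, whose transcription follows a stimulus within minutes, 17 were lower, with a median of -0.38, below all random lists; Klf6 (-1.04), Atf3 (-1.01) and Jun (-0.93), all transcription factors, were lower, and Nr4a1 was 1 of the 2 exceptions. Within single clusters its median was 0.22 in c3 (17 of 19 higher), 0.13 in c9 (15 of 19 higher) and -0.020 in c21 (7 of 17 higher), and the 2 libraries' cells lie mostly in different clusters. Of 13 measured genes of inflammatory cytokines and NF-kB targets, 9 were lower (median -0.53, below all random lists), among them the chemokines Cxcl10 (-1.21, -1.33 to -1.09) and Cxcl1 (-0.92, -1.01 to -0.83), the NF-kB inhibitor Nfkbia (-0.99, -1.07 to -0.90) and the adhesion molecule Icam1 (-0.88, -0.99 to -0.77); within clusters this list was at -0.17 in c3, 0.14 in c9 and -0.0084 in c21. Heat shock genes had a median of -0.28, with 12 of 14 lower, including Hspb1 (-0.67) and Hspa1a (-0.51), and were at -0.16, -0.15 and -0.093 in c3, c9 and c21. Oxidative phosphorylation genes were higher in 36 of 44 cases, by a small median of 0.10 that lay above all random lists; Ndufa1, a subunit of complex I, reached 0.36, and in c3, c9 and c21 the list was at 0.057, 0.0074 and 0.061. The interferon response list had a median of 0.16 at percentile 92.3, inside the range of random lists (-0.11 to 0.21), and ran from -0.14 to 0.15 within c3, c9 and c21.

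The genes with the largest differences included transcripts that Leydig cells do not make. Ighg3, an immunoglobulin heavy chain, had 912 UMIs in EXO Leydig-like cells and 0 in PBS. It was 473-fold higher against a floor of 3 counts, and at least 384-fold by the 95% counting bound. Igkc, the kappa light chain, stood at 89.2 against 0.561 CPM, and Jchain, which joins immunoglobulin units, at 10.1 against 0.217 CPM. No cluster was named as plasma cells, and the same kind of transcripts led the unnamed, shallow cluster c10. Flrt1 (-4.03, -4.89 to -3.29), Fmr1nb (-2.87, -3.50 to -2.30) and the pseudogene Pisd-ps2 (-2.60, -3.01 to -2.21) were lower.

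In stromal-like cells the median gene was 0.26 higher in EXO than in PBS, and the stromal values for this pair are given relative to it. Immediate early genes were the group that stood farthest apart, with 17 of 19 lower before this shift and a relative median of -1.14 (-0.88 before the shift, below all random lists). Jun (-2.09), Socs3 (-1.94), which restrains cytokine signals, Junb (-1.91) and Btg2 (-1.83) led it. Within 5 stromal-like clusters the list ran from -0.41 in c7 to 0.57 in c0 without the shift, higher in EXO in c0, c1 and c6 and lower in c4 and c7; within 4 clusters made without the list's genes it ran from -0.95 to -0.13. The acute-phase gene Saa3 was at 0.366 CPM in EXO against 29.1 in PBS (-6.57, -8.46 to -5.20). Hspa1a, an inducible chaperone, was lower at -1.44. Heat shock genes as a list were at -0.48 (-0.22 before the shift, percentile 0.01), but within the 5 clusters, without the shift, from -0.19 to 0.038. Higher genes were Sfrp1, a secreted Wnt antagonist (1.33, 0.96 to 1.72), the RNA gene Snhg9 (1.30, 1.07 to 1.53) and the chemokine Ccl8 (1.94, 0.95 to 3.08). Extracellular matrix genes were at the level of the median gene as a list (-0.00 relative, 0.26 before the shift), though Lox (1.07), a collagen cross-linker, and Fn1 (0.77), fibronectin, were higher. Within the 5 clusters this list was above the median gene of each, narrowly in c0 (0.17, median gene 0.16) and most in c7 (0.34, median gene 0.089). Its level relative to the median gene therefore depends on the clusters. The interferon list stood at -0.04 relative and 0.22 before the shift. Within the 5 clusters it was above the median gene of each, from 0.12 in c4 (median gene 0.078) to 0.49 in c0 (0.16), and within 4 clusters made without its genes it ran from 0.22 to 0.32, so its place relative to the median gene depends on the clusters.

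Among the largest differences in T or NK cells were 3 genes of effector function. Klrg1, a receptor of differentiated T and NK cells, was higher in EXO than in PBS at 2.91 (2.07 to 3.88), Gzma, a cytotoxic protease, at 2.45 (2.06 to 2.87), and the cytokine Il17a at 1.74 (1.34 to 2.17). Immediate early genes were lower (median -0.22, 15 of 18 lower, below all random lists), led by Fosb (-1.45, -1.61 to -1.30) and Btg2 (-0.85, -0.95 to -0.75). Leydig markers in these cells summed to 4056 CPM in PBS and 2138 in EXO, so RNA of other cells is not excluded for this list. The interferon list was at -0.21 (percentile 1.17, 14 of 19 lower), with Ifit1 at -1.0002 and Isg15 at -0.88; its direction depended on how cells were weighed, since it stood at 0.08 when each cell counted equally. Heat shock genes were at -0.14 (percentile 3.14). H2-Ab1, an antigen-presenting class II gene, was at 4.35 against 26.0 CPM on 7 and 46 UMIs. PBS macrophages were too few for the guard against free RNA and were not tested as a source. Macrophage markers in T or NK cells summed to 39.1 CPM in EXO and 48.6 in PBS, a smaller difference than that of H2-Ab1. Dendritic cell markers, which include H2-Ab1, summed to 57.8 CPM in EXO and 106.2 in PBS. RNA of other cells is therefore not excluded for H2-Ab1. The ribosomal RNA locus CT010467.1 was lower in EXO T or NK cells (-2.53), as it was in stromal-like cells (-3.00 relative), and so was Mir6236 (-2.24). Free germ cell RNA differed too: Ldhc, the lactate dehydrogenase of the testis germ line, was higher in EXO than in PBS by 1.39 in Leydig-like, 1.65 in stromal-like and 1.51 in T or NK cells.

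The third comparison set the dEXO library against the PBS library. Proliferation genes and interferon-induced genes were higher in dEXO in both large interstitial classes, and in Leydig-like cells the cholesterol genes were lower. The proliferation list was higher on very low levels, with 20 of 21 genes higher in Leydig-like cells (median 1.11, percentile 99.96, and 1.01 relative to the median gene) and 16 of 19 in stromal-like cells (1.40, percentile 99.9, and 1.17 relative to the median gene). The mitotic kinase gene Plk1 was at 3.496 against 0.344 CPM in Leydig-like cells, where Mki67, a marker of cycling cells, was at 2.36 (1.81 to 2.94), and Ccnb1, a mitotic cyclin, was at 13.7 against 1.18 CPM in stromal-like cells. Within the only cluster of each class where at least 5 of these genes could be measured, the list was at 0.39 in Leydig-like c3 and at -0.0040 in stromal-like c0. Cluster c22, led by Mki67 and with raised Leydig markers, stayed unnamed and lies outside the Leydig-like sums. It held 56 of 5267 PBS, 117 of 9860 EXO and 58 of 8970 dEXO cells. Its share was lowest in dEXO, against the direction of the list. Germ cells carry these transcripts too (Plk1 at 84.7 CPM in dEXO spermatogonia), and free germ cell RNA differed in the same direction, with Ldhc at 2.998 and 3.10 in the 2 classes. Of 21 interferon response genes in Leydig-like cells 20 were higher, with a median of 0.59 at percentile 99.98, but of 0.29 within c3 and 0.12 within c21. In stromal-like cells 18 of 20 were higher, with a median of 0.60, above all random lists, and of 0.37 relative to the median gene, which was itself 0.23 higher. Most PBS Leydig-like cells lay in cluster c9 (921 cells) and most dEXO ones in c2 (1665 cells).

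**Figure D3:**
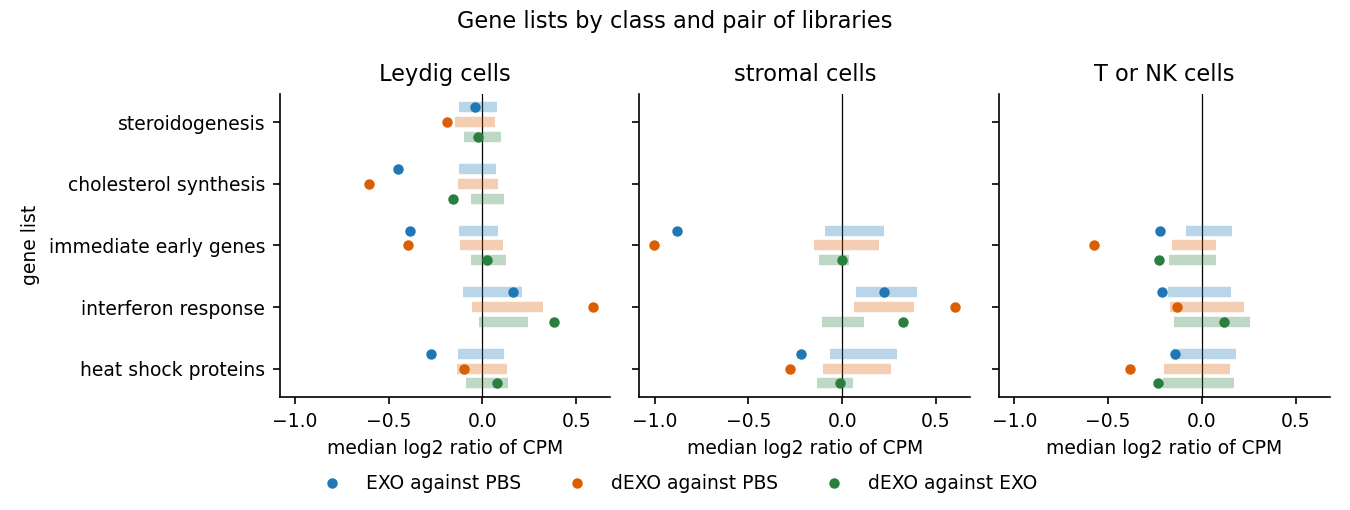
Median log2 ratio of CPM (x axis) of 5 gene lists (y axis) in Leydig-like, stromal-like and T or NK cells, 1 point per pair of libraries; pale bars are the central 95% of 10000 random lists of the same size and expression. Immediate early genes lie at -1.0004 and interferon genes at 0.60 in stromal-like cells for dEXO against PBS.

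Interferon genes farthest apart in Leydig-like cells were Rtp4, a chaperone of receptors, at 1.71 (1.42 to 2.01), Ifit3 at 1.27 (0.95 to 1.59), Ifi44 at 1.25 (0.54 to 1.96) and Ifit1 at 0.87 (0.55 to 1.20); their levels were low, with Rtp4 at 9.25 CPM in dEXO and 2.82 in PBS. In stromal-like cells, relative to the median gene, the antiviral gene Rsad2 was at 1.90, Ifit1 at 1.14, Oasl2 at 1.13 and Rtp4 at 0.96. The largest differences there also included 2 interferon-inducible GTPases, Iigp1 (1.38, 1.17 to 1.58) and Irgm2 (1.13, 0.82 to 1.45), with the cyclin-like gene Ccnyl1 (1.42, 0.89 to 1.97). T or NK cells did not share this: their interferon list was at -0.13 (percentile 5.29), with Ifit1 at -1.05 and Xaf1 at 0.73. In T or NK cells Ldhc was higher in dEXO than in PBS by 2.98.

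All 19 cholesterol synthesis genes were lower in dEXO than in PBS Leydig-like cells (median -0.60, below all random lists). Mvd was at -1.44 (-1.57 to -1.32), the sterol sensor Insig1 at -1.16 (-1.23 to -1.09) and Idi1 at -1.04 (-1.10 to -0.99). Of 17 steroidogenesis genes 12 were lower, with a median of -0.19 at percentile 0.22 (-0.29 relative to the median gene); within clusters the median was -0.10 in c3 and -0.069 in c21, where the median gene was at -0.057. The cholesterol list was at -0.52 in c3 and -0.56 in c21. Star (chromosome 8, 25806555 to 25815982) was at -1.20 (-1.22 to -1.17), from 1507 CPM in PBS to 657 in dEXO, Fdx1, the electron donor of mitochondrial P450 enzymes, at -0.67 (-0.69 to -0.65), Por at -0.77 and Srd5a1 at -0.84, the last with intervals that held 0 in c3 (-0.31, -0.98 to 0.29) and c21 (-0.81, -1.87 to 0.13). Hsd3b1 went the other way at 1.39 (1.37 to 1.41). Only the Leydig-like clusters c3 and c21 had 50 cells or more in both libraries. Star was lower and Hsd3b1 higher in dEXO in both, at -0.99 and 1.18 in c3 and at -1.12 and 1.42 in c21. These clusters held 93 and 82 of the 1842 dEXO Leydig-like cells, so most of the class was not compared within clusters. Hsd3b1 was also the first leading gene of c2, which held 1665 dEXO cells, so the clusters may have been drawn in part by it.

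**Figure D4:**
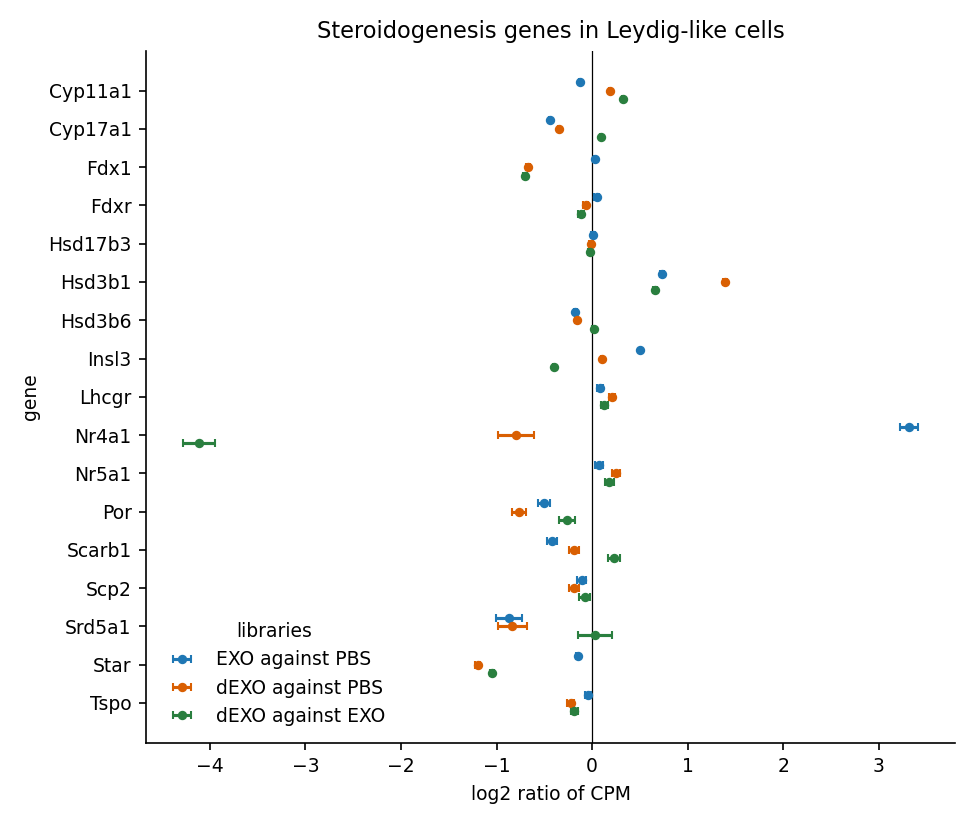
Log2 ratio of CPM (x axis) of 17 steroidogenesis genes (y axis) in Leydig-like cells, 1 point per pair of libraries with its 95% counting interval as a bar. Nr4a1 is at 3.31 for EXO against PBS and at -4.11 for dEXO against EXO, and Star at -1.20 for dEXO against PBS.

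Targets of p53, the damage-responsive transcription factor, were lower as a list in dEXO than in PBS Leydig-like cells (median -0.27, 13 of 18 lower, below all random lists). The cell-cycle inhibitor Cdkn1a was at -1.71 (-1.80 to -1.62), the nuclease Aen at -1.13 (-1.28 to -0.99) and Phlda3 at -0.90 (-1.04 to -0.76). Within c3 and c21 the list was at -0.40 and -0.84. Immediate early genes were lower in the class as a whole (19 of 19, median -0.40), with Atf3 at -0.81, Nr4a1 at -0.79, Egr1 at -0.78 and Fosb at -0.61. Within the 2 clusters with 50 cells in both libraries the list was near 0, at 0.0050 in c3 (9 of 18 higher) and 0.058 in c21 (10 of 16 higher), with Nr4a1 at -0.80 (-2.03 to 0.20) and 0.037 (-0.73 to 0.76). Heat shock genes had a median of -0.10 at percentile 7.67, with Hspa1b at -1.10 and Hspa1a at -0.94. Saa3 was 16.6-fold higher in dEXO (33.6 against 2.03 CPM), the opposite of its direction in stromal-like cells. The muscle gene Tcap (3.20, 2.13 to 4.42) and Nrep (2.33, 2.09 to 2.57) were higher. Mfsd2a, a lipid transporter (-5.02, -5.93 to -4.24), Aqp5, a water channel (-4.59, -5.10 to -4.12), and Heyl, a Notch target (-4.33, -5.25 to -3.54), were lower.

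In stromal-like cells all 19 immediate early genes were lower in dEXO than in PBS, with a median of -1.0004, below all random lists, and of -1.23 relative to the median gene. Within single clusters, without the shift, it ran from -0.37 to 0.38, and within clusters made without the list's genes from -1.14 to 0.021. Relative values were -1.82 for Jun (-1.88 to -1.75), -1.78 for Junb (-1.85 to -1.72), -1.75 for Socs3 and -1.74 for Btg2. Saa3 was at -5.39 (-7.02 to -4.15), on 0.817 against 29.1 CPM. Heat shock genes were at -0.51 relative (-0.28 before the shift, below all random lists), with Hspa1a at -1.38, but from -0.21 to -0.028 within the 5 clusters without the shift. Extracellular matrix genes were at -0.05 relative and 0.18 before the shift, with Fn1 at 0.68 relative. In T or NK cells immediate early genes were at -0.57 (17 of 18 lower, below all random lists) and heat shock genes at -0.39 (10 of 11 lower, percentile 0.06). Leydig markers summed to 4056 CPM in PBS and 2245 in dEXO T or NK cells, so RNA of other cells is not excluded for these lists. Hspa1a (-2.14, -2.72 to -1.61), Fosb (-1.17), Egr1 (-1.003) and Plac8 (-1.71, -2.12 to -1.32) were lower there. The chemokine Ccl1 (3.95, 3.23 to 4.76) and the NK receptors Klra1 (3.08, 2.28 to 3.99) and Klra9 (3.18, 2.20 to 4.32) were higher; Klra genes are close paralogs, so reads may be hard to assign among them. CT010467.1 was at -1.33.

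The fourth comparison set the 2 exosome sources against each other, dEXO against EXO. Leydig-like cells of dEXO had far less Nr4a1, less Star and more interferon-induced RNA, and stromal-like cells and macrophages also had more interferon-induced RNA. Nr4a1 was at 10.999 CPM in dEXO and 189.7 in EXO (-4.11, -4.28 to -3.94). Within single Leydig-like clusters it was at -4.41 in c2, -4.64 in c3 and -2.19 in c21. Star was at -1.05 (-1.07 to -1.02), Fdx1 at -0.70 and Insl3 at -0.40, while Hsd3b1 was at 0.66 and Cyp11a1, which makes the first step from cholesterol, at 0.32. The whole steroidogenesis list had 8 of 17 genes higher and a median of -0.02 at percentile 27.3, or -0.12 relative to the median gene. Cyp17a1 was at 0.09, and at -0.01 relative to the median gene, but at 0.33 in c2, 0.21 in c3 and 0.20 in c21; Insl3 was at -0.18, -0.37 and 0.046 there.

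Interferon response genes were higher in dEXO than in EXO in 20 of 21 cases in Leydig-like cells (median 0.38, percentile 99.97), in 20 of 20 in stromal-like cells (0.32, above all random lists) and in 13 of 14 in macrophages (0.55, percentile 99.99). Within Leydig-like clusters the list was at 0.12 in c2 (12 of 20 higher), 0.25 in c3 and 0.22 in c21, and in 4 clusters made without its genes from 0.15 to 0.37, less than over the whole class; in 4 stromal-like clusters it ran from 0.21 to 0.42, and in 4 made without its genes from 0.17 to 0.43. Rsad2 was at 1.20 (0.75 to 1.66) in Leydig-like and 1.40 (0.72 to 2.11) in stromal-like cells, and Ifit3 at 1.33 and 0.69. In macrophages Zbp1, a sensor of nucleic acids, was at 1.34 and Isg15 at 1.16. Leydig markers there summed to 1314 CPM in EXO and 2588 in dEXO, so RNA of other cells is not excluded in macrophages. T or NK cells were at 0.12 (percentile 77.4). Ldhc was again higher, by 1.61 in Leydig-like, 1.44 in stromal-like and 1.47 in T or NK cells.

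Other Leydig-like groups were lower in dEXO than in EXO. Oxidative phosphorylation genes were lower in 38 of 44 cases (median -0.22, below all random lists), with Ndufa1 at -0.47 and Ndufb2 at -0.39; the list was at -0.093 in c2, -0.17 in c3 and -0.084 in c21. Cholesterol synthesis was at -0.16 (16 of 19 lower, percentile 0.02), with Idi1 at -0.73, and at -0.27, -0.19 and -0.23 in these clusters. The p53 list was at -0.21 (12 of 18 lower, below all random lists), with Cdkn1a at -1.08 but the pro-apoptotic Bbc3 at 1.23, and the list at -0.42, -0.32 and -0.41 in them. Immediate early genes were level over each whole class (0.03 in Leydig-like and 0.00 in stromal-like cells), but in c2, which held most dEXO Leydig-like cells, all 19 were lower (median -1.17), against -0.14 in c3 and 0.18 in c21. These clusters were drawn in part by the list itself: in clusters made without its genes the medians were -0.23 in n3, which held 1612 dEXO cells (4 of 19 higher), -0.21 in n4 and 0.091 in n19. In the stromal-like class they ran from -0.24 to 0.17 in the 5 clusters first made and from -0.28 to 0.17 in those made without the list. Proliferation genes were higher, at 0.79 in Leydig-like cells (20 of 22 higher, percentile 99.98) and 0.78 in stromal-like cells (14 of 20 higher, percentile 99.98). Within clusters they were at 0.52 in c2 and 0.49 in c3, and at 0.51 in stromal-like c0 but -0.13 in c1 (3 of 7 higher). The unnamed cycling cluster c22, outside these sums, held 117 of 9860 EXO and 58 of 8970 dEXO cells. Level over the whole classes were also heat shock genes (0.08, or -0.02 relative to the median gene, and -0.01), which were at -0.096 in c2, 0.085 in c3 and -0.15 in c21. Saa3 was 5.15-fold higher in dEXO, Txnip, which binds thioredoxin, was higher at 1.93 (1.89 to 1.96) and the small GTPase Gem at 1.80. Mfsd2a was at -6.09 (-7.01 to -5.31), Igkc at -5.64 and Ighg3, with 0 UMIs in dEXO, 235-fold lower against the same floor (at least 191-fold by the counting bound). In stromal-like cells Iigp1 was at 0.95, Lars2 at 0.88, CT010467.1 at 1.24, Rasd1 at -1.33, Nr4a1 at -1.22 and Adamtsl2 at -2.89. T or NK cells had more Ccl1 (3.44), Klra7 (2.62) and Klra1 (2.21) and less Klrg1 (-2.94), Gzmk (-1.77) and Ccl5 (-1.11, -1.16 to -1.05) in dEXO. Their immediate early genes were at -0.23 (percentile 0.29), with Fos at -0.52, and their heat shock genes at -0.24 (percentile 1.09).

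With at least 100 cells asked of both libraries, germ stages and Sertoli-like cells could be compared only between dEXO and EXO. In spermatids 23 of 30 sperm flagellum genes were higher in dEXO (median 0.17, percentile 99.96, and 0.20 in c11 and 0.17 in c19), including the dynein heavy chains Dnah8 (0.62, 0.50 to 0.74) and Dnah17 (0.58, 0.39 to 0.77) and Smcp (0.41). Of the genes that condense the nucleus and build the acrosome 14 of 26 were higher (median 0.05, percentile 95.4, and -0.01 relative to the median gene). Prm2, a protamine that packs sperm DNA, was at 0.99 (0.94 to 1.05), Tnp2 at 0.47 and Prm1 at 0.75, but Prm1 was at -0.26 when each cell counted equally. Hyal1, a hyaluronidase, was higher in spermatids (1.25, 0.97 to 1.54) and in late spermatocytes (1.21, 0.85 to 1.60). Paqr5 (1.44) and Prima1 (2.34) were higher and Tmed6 (-0.88), Fxyd2 (-0.89) and Defb14 (-1.01) lower in spermatids.

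Late spermatocytes of dEXO had more RNA of DNA crosslink repair genes, the kind of lesion that busulfan makes, with 21 of 25 higher and a median of 0.36 at percentile 99.8. Brip1 was at 1.101 (0.21 to 2.10), Eme1 at 0.82 and Fancm at 0.68, on few UMIs each, 57 and 13 for Brip1. The mix of stages differed too: cluster c14 held 137 of 365 late spermatocytes in EXO and 296 of 647 in dEXO, early spermatocyte markers summed to 923 CPM in EXO and 1187 in dEXO, and spermatid markers to 5748 and 4517. Within clusters the repair list was at -0.072 in c14, 0.11 in c18 and 0.25 in c23, nearer 0 than in the whole class. Meiosis genes were at 0.20 there (percentile 94.9, 18 of 26 higher, from 0.038 to 0.19 within clusters), with Sycp1 of the synaptonemal complex at 0.65 and Syce3 at -0.49, and at -0.01 in early spermatocytes (percentile 47.4). Zfp389, a pseudogene, was at 1.502, Cep112it at 1.51, the DNA polymerase subunit Pole2 at -1.09, the histone gene H2afb3 at -1.04 and Spaca5 at -0.98. In Sertoli-like cells, blood-testis barrier genes were lower in 15 of 18 cases (median -0.14, percentile 0.62), with the tight-junction gene Ocln at -0.41 but Cldn3 at 0.89 (0.60 to 1.17). Free RNA, estimated at 8.17% of UMIs in dEXO and 1.40% in EXO Sertoli-like cells, is not excluded there: Leydig markers summed to 2325 CPM in EXO and 3578 in dEXO, late spermatocyte markers to 458 and 850, and Ldhc was at 1.40. These estimates were set by markers of different classes, dendritic cells in dEXO and B cells in EXO, so they are not strictly comparable. T or NK markers went the other way, with 40.01 CPM in EXO and 27.5 in dEXO. Genes of Sertoli secretion and identity were higher in 17 of 24 cases (median 0.07, and -0.09 when each cell counted equally). Niche factors for spermatogonia were at -0.02, with Cyp26b1, which degrades retinoic acid, at -1.60 (-1.90 to -1.30) and the Kit ligand Kitl at -0.41 (-0.57 to -0.25). Cyp26b1 was also a leading gene of stromal-like c0, which held 1588 EXO and 839 dEXO cells. Stromal markers summed to 492 CPM in EXO and 458 in dEXO Sertoli-like cells, so stromal RNA is not excluded for Cyp26b1.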

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

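No paired analysis was possible because there was 1 library per group and replicate numbers in the labels are only names. Of 99 alternative values of the main results 59 stayed inside the counting interval, 40 moved and 0 reversed; for the shares of other classes the numbers were 222, 210 and 0 of 432, for other gene lists 127, 51 and 8 of 186, and for single genes 1205, 296 and 9 of 1510. For shares, the rule could only label a value as inside the interval or moved, so their 0 reversed was fixed beforehand. Among the main results only the steroidogenesis medians could be labelled reversed, where their counting interval excluded 0. The order PBS, EXO, dEXO of the germ cell share held in 16 of 16 alternatives, of which the second naming rule and c28 counted as germ cells gave the same shares. Germ cell shares in percent that moved, in that order, were 3.27, 10.4 and 20 with the first naming rule; 4.79, 13.03 and 24.9 with all barcodes; 5.30, 9.15 and 14.6 with each library clustered alone; 5.30, 13.3 and 25.9 with cells named one by one; 3.495, 7.83 and 15.7 without c11 and c17; 5.001, 14.2 and 26.5 without unnamed cells; and 0.272, 0.733 and 1.20 as the share of all UMIs from germ markers. The PBS share was 5.05 with the second naming rule and with c28 counted as germ cells, 5.07 at Leiden resolution 0.5 and 5.15 with 4000 variable genes. At resolution 2 EXO and dEXO were 9.15 and 17.9, with the stricter filter 8.29 and 16.6; without the highest doublet scores PBS and dEXO were 5.29 and 24.1; thinned EXO was 11.4. The naming rules, c11 and c17, c28, unnamed cells, c3 alone and c5 were chosen after seeing the data. Steroidogenesis medians, EXO against PBS, were -0.0755 with the first naming rule, -0.0023 with each library clustered alone, -0.0738 with cells named one by one and -0.0694 with c5 added. For dEXO against PBS they were -0.29 relative to the median gene, -0.21 with each library alone and -0.10 in c3 alone, and for dEXO against EXO -0.12 relative to the median gene. Reversed relative to the median gene were stromal-like extracellular matrix (EXO against PBS -0.0013, dEXO against PBS -0.0533) and interferon (EXO against PBS -0.0377), and for dEXO against EXO heat shock in Leydig-like cells (-0.022), spermatid condensation (-0.0128) and Cyp17a1 in Leydig-like cells (-0.0097). Reversed with cells weighted equally were interferon in T or NK cells (EXO against PBS 0.0828), Sertoli secretion (dEXO against EXO -0.0943), Fdx1 in Leydig-like cells (EXO against PBS -0.0020), Idi1 in Sertoli-like cells (dEXO against PBS 0.87), and for dEXO against EXO Rnf212 in early spermatocytes (0.77) and Prm1 in spermatids (-0.26). Fdx1 in Leydig-like cells (EXO against PBS) was -0.0173 with no doublet removed, and macrophages (dEXO against PBS) then had 0.0425 for proliferation, 0.0434 for Mki67 and 0.0425 for Top2a; Ldhc in Sertoli-like cells (dEXO against EXO) -0.24 with free RNA subtracted. For the main results that moved, the cause was not tested.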

Other observations

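Of the tests below, the thinning, germ to Sertoli and scaling tests, the test across tubule classes, the test of germ stages and the clusterings without a list's genes were chosen only after the result was seen; the comparisons with PBS in classes under 100 cells were added then too, and the germ to Sertoli tests and the interferon tests without the list's genes and the test across tubule classes were split and made stricter after a first value had been seen. Sertoli-like cells (81 in PBS, 228 in EXO, 536 in dEXO) had less RNA of cholesterol synthesis and of antigen presentation in both exosome libraries than in PBS, but the PBS cells also held more RNA of other cells: Leydig markers summed to 10439 CPM in PBS, 2325 in EXO and 3578 in dEXO, and T or NK markers to 136 CPM, 40.01 and 27.5, so RNA of other cells is not excluded for either list. All 15 measured cholesterol synthesis genes were lower in EXO (median log2 ratio -0.66, below every one of 10000 random lists) and all 17 in dEXO (-0.76, below all). Fdps was at -1.78 (-2.20 to -1.37) in EXO and -1.44 (-1.75 to -1.12) in dEXO. MHC class I genes were lower in 5 of 5 cases in EXO (-0.77) and 6 of 6 in dEXO (-0.78), with H2-D1 at -1.06 and -1.18 and B2m at -0.77 and -0.62. Spermatogonia were nearly level in proliferation genes, at -0.03 in EXO and -0.03 in dEXO, with Mcm3, a replication helicase subunit, at -0.38 and -0.24. Ldhc was higher by 1.02 and 2.42 in Sertoli-like cells and by 1.64 and 2.86 in spermatogonia.

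Macrophages of c16 (87 in PBS, 179 in EXO, 143 in dEXO) had more interferon-induced RNA in dEXO than in PBS. Of 14 interferon genes 13 were higher, with a median of 0.73, above all random lists. In EXO the median was 0.18 at percentile 96.5, with 9 of 12 higher. Ifitm3, which blocks viral entry, was at 1.15 (0.91 to 1.39) in EXO and 1.62 (1.38 to 1.86) in dEXO, and Bst2, which tethers virions, at 0.94 and 1.33, but Isg15 was at -0.90 in EXO. Immediate early genes were lower in 16 of 16 cases in both libraries (-0.59 and -0.75, below all random lists), with Fosb at -1.28 and -1.07 and Atf3 at -0.84 and -1.22. Only 6 proliferation genes could be measured, at medians of -2.01 and -1.93; with no doublet removed the dEXO median was 0.0425. Ldhc was higher in macrophages by 1.43 in EXO and 2.85 in dEXO. Leydig markers in macrophages summed to 712 CPM in PBS, 1314 in EXO and 2588 in dEXO, and Sertoli markers to 272, 581 and 1169. RNA of other cells is therefore not excluded for these lists.

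Germ cells were more abundant in EXO and dEXO than in PBS, which the injected exosomes could account for. Unequal depth argues against itself as the cause, since with all cells thinned to 1000 UMIs the EXO share was still 2.72 times that of PBS, and so does the naming of cells, since germ markers took 2.70 times as large a share of all EXO UMIs as of PBS UMIs. A rise of all germ stages alike, as more tubule tissue of the same kind would give, is argued against for dEXO against PBS. The odds ratio of spermatogonia to later germ cells was 0.248 there, with its interval below 1 in 11 of 11 other settings. The second naming rule and c28 counted as germ cells gave the same counts. All settings name cells of the same libraries, so they are not independent of each other. Such a rise stays open for EXO against PBS, where the ratio was 0.242. Its interval was below 1 in 10 of 11 other settings, but held 1 with each library clustered alone (0.749, 0.558 to 1.0064). For dEXO against EXO (1.02) it stays open too. In 3 more settings, the thinned one among them, no spermatogonia were named, so depth was not checked here. More germ and Sertoli-like cells together stay open against PBS, since the odds ratios of germ to Sertoli-like cells, 1.98 for EXO and 1.46 for dEXO, had intervals above 1 in 10 and 3 of 13 other settings, and between dEXO and EXO the ratio was 0.740, below 1 in 13 of 13, so the higher dEXO share may come from the amount of tubule tissue captured. With 1 library per group, animals and preparations cannot be told apart from the injections.

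Interferon genes were higher in dEXO than in PBS in Leydig-like and stromal-like cells, and a response to exosomes of mice with an imbalanced microbiota is a candidate explanation that was not tested apart from the animal. Once the estimated free RNA was subtracted, the medians stayed at 0.61 in Leydig-like and 0.63 in stromal-like cells. RNA of other cells is not excluded by this. The estimate was set by markers of different classes in PBS and dEXO, and it does not cover doublets. Late spermatocyte markers summed to 194 CPM in PBS and 1172 in dEXO stromal-like cells. How much of them the subtraction removed is not given here. Scaling is argued against, since the medians were 0.49 and 0.37 relative to the median gene. A shift in which stromal-like cells were captured is also argued against: in 4 clusters made without the list's genes the medians ran from 0.40 to 0.60. In Leydig-like cells it stays open, since only 2 such clusters held 50 cells in both libraries, at 0.12 and 0.22 with intervals that include 0. In the first clustering, where 7 of the 24 list members were among the variable genes, the medians of 7 clusters ran from 0.12 to 0.81, which decides neither way.

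Immediate early genes were higher in PBS than in both exosome libraries in interstitial cells, which stress during dissociation of 1 sample or a difference between the injections could give. After subtraction of the estimated free RNA the stromal-like median was -0.98 for dEXO against PBS. RNA of other cells is not excluded by this, since markers of different classes set the estimate in the PBS and dEXO libraries. EXO against PBS was not tested this way. A rise in every cell of the PBS library as large as in stromal-like cells is argued against by spermatogonia, spermatids and Sertoli-like cells. Their lowest bounds relative to the median gene were -0.30 in EXO and -0.42 in dEXO. The upper bounds of stromal-like cells were -0.73 and -0.97, with medians of -1.14 and -1.23. These bounds measure the spread over the list's members, not over cells or libraries. A smaller rise stays open, since the lowest medians of the tubule classes were -0.077 and -0.054 (-0.12 and -0.14 relative) with spreads that pass -0.2. A different mix of cells stays open: in Leydig-like cells, clustered without the list's genes, dEXO and PBS shared 1 cluster of enough cells, where the median was 0.025, and in the 3 such clusters shared by EXO and PBS it ran from 0.0012 to 0.44, with none below 0. Within the 5 stromal-like clusters first made the medians ran from -0.37 to 0.38, with 3 above -0.2, the outcome set beforehand for such a mix, but 15 of the 19 list genes had been used for the clustering, so those clusters were in part drawn by the list itself and the test is void. In 4 stromal-like clusters made without these genes the medians ran from -1.14 to 0.021 for dEXO and from -0.95 to -0.13 for EXO, and 1 was above -0.2 in each.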
